A study of Mus musculus with 15 samples.

How the data were processed

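The samples were small-intestinal crypts from mice aged 6 to 8 weeks, taken 24 h after a control IgG antibody, a single dose of Notch1 and Notch2 blocking antibodies, or those antibodies with 30 mg/kg of an Lrp6 antibody. The labels give the Notch antibody dose as 1 mg/mL, which is a concentration, and the amount per animal is not given in the sources used here. Each group had 5 arrays, which the series design calls biological replicates. Whether each array holds 1 animal or a pool is not given in the sources used here.

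Per the labels' protocols, intestines were cut up and shaken in a chelating buffer to release crypts, which were passed through a strainer and pelleted. Total RNA was amplified and labelled with Cy5 (red) and hybridised against a Cy3-labelled (green) universal mouse reference on 2-colour Agilent arrays, with no dye swap. Per the file headers, the arrays were read with Feature Extraction 11.0.1.1 and the probes were designed on mouse build mm9. The scanner files that the authors deposited give for every spot the raw median intensity and median local background intensity of both channels, a log10 ratio of red over green after the software's own background subtraction and dye normalization, and quality flags. No mean intensity columns were in the files, so median intensities were used in place of the means planned. The authors also deposited a table of log2 values, 1 column per array, whose processing is not described there beyond R 3.0.0 and limma 3.6.7 in the submitters' processing notes. Set against the values computed here, its columns correlated at r of at least 0.99998 with the same sign on every array, with slopes from 0.999 to 1.003. Its scale and direction are therefore log2 of crypt over reference, and the medians of its columns lay between 0.0144 and 0.0286.

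Calculations were made in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Each array held 44397 spots. Background was corrected with normexp (offset 50) and log2 ratios of red over green were normalized within arrays by loess, with control spots at weight 0 and then left out. Spots carrying the scanner's flags for non-uniformity or population outliers were left out, between 299 and 428 per array. Spots of the same probe were averaged. A probe was kept when it was well above background in red on at least 4 of the 5 arrays of at least 1 group, which left 28488 of 39429 probes. Gene names are those of the array files, with accessions looked up without version in a RefSeq table of assembly GRCm38.p6, used for names only. Of the probes, 26581 had a gene name and 12848 had none and stayed as features of their own. For the 3838 genes with several probes, the probe with the highest mean red signal stood for the gene. This gave 23937 features, 16057 of them named, and 368 lacked a value on 1 array.

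The background step was corrected after a first set of results had been seen. At first, spots flagged for an uneven local background entered the normexp fit. On 4 arrays, 16 such spots in all, between 1 and 6 per array, had backgrounds far above their foreground (difference down to -12644). They raised the fitted spread of the background to as much as 211, against at most 3.36 on the other 11 arrays, and compressed the ratios there. The fault showed when the columns of the deposited table correlated at only 0.954 to 0.979 with those 4 arrays. The plan left flagged spots out without saying at which step. Leaving them out before the fit, a step chosen after those results, brought the largest fitted spread to 3.23. All values given are from the corrected version, and the first version, whose counts were known by then, is among the alternatives.

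The 3 groups were compared in 1 limma fit of the 15 arrays (lmFit and eBayes), so that they share 1 estimate of the spread. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. Changes are differences of group means on the log2 scale, given with the fit's SE. Group, comparisons, test, filter, 18 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists are Notch targets and receptors, secretory progenitor genes, a stem cell signature, Wnt targets, Wnt receptors and ligands, markers of goblet, Paneth, enteroendocrine, tuft, enterocyte, immune and stromal and muscle cells, cell cycle, p53, unfolded protein response, interferon, epithelial defence and injury, and immediate early and heat shock genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were the checks. Of the calls, only those of the secretory progenitor and goblet lists in the first comparison and of the secretory progenitor and Notch lists in the third held with an estimated correlation. Fry, which does not set a list against the other genes, passed every list called in the first comparison. In the second it passed the called lists except the enterocyte and stromal lists. In the third it passed the called lists except the cell cycle, enteroendocrine and immune lists.

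The named genes were the antibody targets and 13 index genes whatever their result, the 6 genes with the largest rise and the 6 with the largest fall per comparison, and up to 4 members of lists that passed or held a gene past the threshold. The largest changes were taken among genes past the threshold whose 2 groups did not overlap and that were well above background on at least 4 of 5 arrays of the higher group, leaving out clone and predicted names. A gene named by this rule in 1 comparison is also given in others, and not every gene the rule picks is printed. Olfm4, an index gene, matched no named probe and has no value. For a gene not well above background on any array of a group no fold is given.

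The fit and camera were tested on simulated data made from the real spread. For N1N2 against control, with 200 of 23937 genes changed, 47.8% of changes of 0.5 on the log2 scale were recovered, 92.5% of changes of 1 and 98.5% of changes of 2, with 16 false calls. These stand beside at most 200 true calls, in a single simulated data set. The fit was thus not shown to hold the share of false calls to its threshold. Camera found the shifted list and none of the other 17. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes are correlated. No pair of arrays held identical values. Alternatives covered background correction, normalization within and between arrays, the red channel alone, the deposited table, the filter, flagged spots, the choice of probes, the samples in the fit, replicate number and slide as blocks, array weights, the prior, stricter thresholds and leaving out each array. Among them 3 were chosen after seeing the data: the first normexp version, the stromal mean as a covariate, and a joint omission of arrays. The arrays omitted were the late-scanned one and the one with the fewest spots above background in red.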

Results

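Gene expression was measured in crypts isolated from the small intestine of mice aged 6 to 8 weeks. Crypts are the epithelial pits that hold the intestinal stem cells, their dividing progeny and the Paneth cells. Mice had received a control IgG antibody, blocking antibodies against the receptors Notch1 and Notch2 (the N1N2 group), or the same Notch antibodies together with 30 mg/kg of an antibody against Lrp6, a co-receptor for Wnt ligands (the N1N2 plus Lrp6 group). Crypts were taken 24 h after treatment, and each of the 3 groups had 5 biological replicates, each on its own array. Every array carried crypt RNA in the red channel and a common mouse reference RNA in the green channel, so that values are log2 ratios of crypt over reference. After the filter on dim probes, 23937 features were compared, of which 16057 had a gene name. Counts of genes over all features, as given below, include features without a name.

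Between 57.2% and 79.8% of the spots were well above background in the red channel, and no spot was saturated. The share was 75.8% ± 4.19 in the control group, 73.9% ± 3.05 in the N1N2 group and 64.8% ± 6.01 in the N1N2 plus Lrp6 group (SD, n = 5 each). In the last group it was 73.6% on replicate 5, which lay on a slide of its own. On the others of that group, which shared a slide, it was 57.2% to 66.9%. Stromal and muscle markers, which come from cells other than the crypt epithelium, had a mean log2 ratio of -1.99 ± 0.28 in the control group, -2.27 ± 0.10 in the N1N2 group and -2.70 ± 0.31 in the N1N2 plus Lrp6 group (SD, n = 5 each). The arrays lay on 6 slides, and 1 slide held both control arrays (2) and N1N2 arrays (2). All other slides held a single group, so slide and group could be separated only for N1N2 against control. The number of arrays limits the precision of every value given here.

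The first comparison addressed what blocking Notch1 and Notch2 does to the crypt transcriptome. Genes that mark the commitment of crypt cells to secretory lineages rose strongly. Neurog3, the transcription factor that specifies enteroendocrine cells, was 14.2-fold higher in the N1N2 group (log2 change 3.83 ± 0.27 SE, adjusted p = 8.5e-07, n = 5 per group). Atoh1, the master regulator of secretory fate, was 3.87-fold higher, Spdef 3.74-fold, Dll1 3.50-fold and Pax4 3.89-fold. Hes1, the Notch target that represses Atoh1, fell by 0.87 on the log2 scale (SE 0.13, adjusted p = 0.00066). The values of all these genes did not overlap between the 5 N1N2 and the 5 control arrays. In all, 1572 features rose and 1233 fell in the N1N2 group at an adjusted p under 0.05, and 208 of those that rose and 58 of those that fell changed at least 2-fold. Of these 2805 features, 2107 had a gene name.

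**Figure D1:**
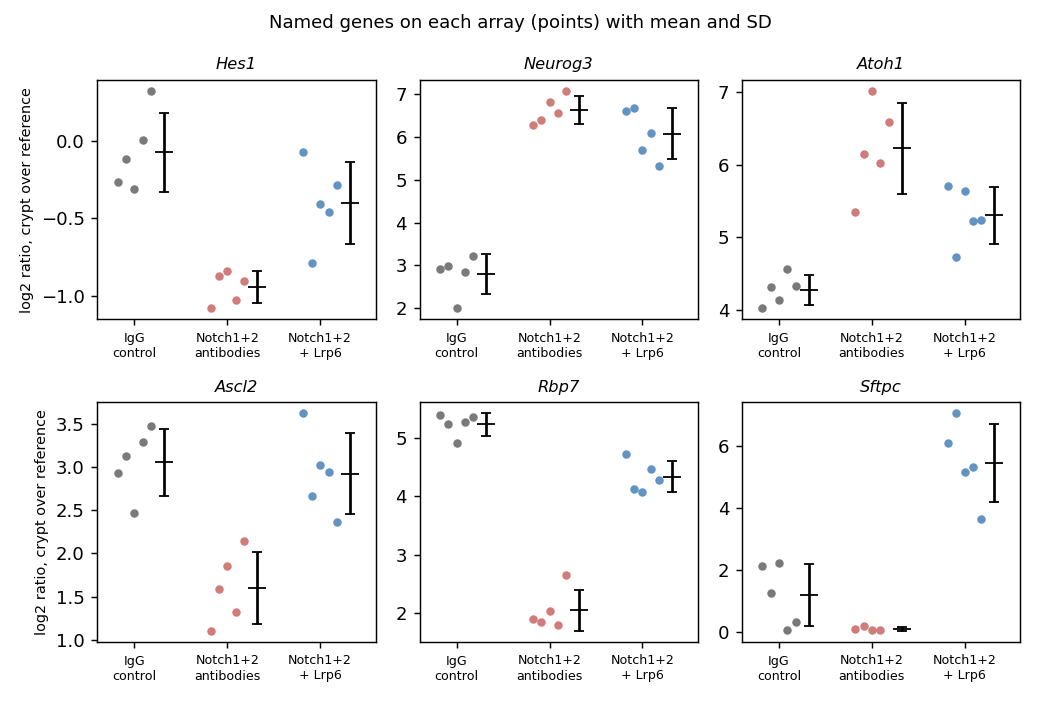
Log2 ratios of crypt over reference RNA (vertical axes) for 6 named genes in the control, N1N2 and N1N2 plus Lrp6 groups; points are single arrays, the bar beside them is the mean and the whisker its SD. For Neurog3 the group means are 2.79, 6.62 and 6.08; for Rbp7 they are 5.23, 2.05 and 4.34; Sftpc has a value on 4 of the 5 N1N2 arrays.

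Of the 13 secretory progenitor genes, 10 rose and none fell in the N1N2 group, both over all genes and adjusted over the list alone (camera adjusted p = 1.1e-16). The members that rose included Gfi1, a factor of goblet and Paneth cell development, by 1.79 on the log2 scale, and Sox4 by 1.53. Goblet cell markers rose in 10 of 18 cases over all genes and in 15 adjusted over the list alone, and none fell (camera adjusted p = 3.5e-14). Among them were Creb3l4 (log2 change 1.65), Creb3l1 (1.63), Sytl2 (1.61) and Pdia5 (1.51), whereas Muc2, the main goblet cell mucin, changed by 0.41 and did not pass the test (adjusted p = 0.29). Both lists held with an estimated inter-gene correlation, with adjusted p = 0.012 for the secretory progenitor genes and adjusted p = 0.037 for the goblet cell markers. The median of the goblet list ranged from 0.13 to 1.25 across the alternatives, and the list passed in each. Within the slide that held both groups, the median log2 change was 1.31 for the secretory progenitor genes and 0.56 for the goblet cell markers, against 1.74 and 0.60 over all arrays. With slide as a block the difference rests on that slide alone, so these medians were the same by construction. Both lists passed there with camera at the preset correlation (adjusted p = 3.4e-11 and 3.8e-10). Camera with an estimated correlation was not run with the block for any list.

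Genes of the unfolded protein response rose in 10 of 16 cases over all genes and in 12 adjusted over the list alone, and none fell (camera adjusted p = 1.2e-09). Ern2, the stress sensor found in mucus-secreting epithelia, rose by 1.81 on the log2 scale, the chaperones Pdia6 by 1.14 and Pdia4 by 1.04, and Atf4 by 0.71. The list call did not hold with an estimated correlation (adjusted p = 0.16 with an estimated correlation). Cell cycle genes moved the other way: 17 of 25 fell over all genes and 20 adjusted over the list alone, and none rose (camera adjusted p = 5.4e-12). Mcm3, a subunit of the replicative helicase, fell by 0.84, Mcm6 by 0.80, Ccna2 by 0.76 and Birc5 by 0.60 on the log2 scale. Mki67, a general marker of cycling cells, changed by 0.13 and did not pass the test (adjusted p = 0.65). This list call too was lost (adjusted p = 0.21 with an estimated correlation). With fry the unfolded protein response and cell cycle lists passed (adjusted p = 0.0015 and 0.0046). Over all arrays the medians were 0.74 for the unfolded protein response and -0.55 for the cell cycle genes. With slide as a block, and by construction equally within the shared slide, they were 0.79 and -0.77. Camera at the preset correlation gave adjusted p = 9.4e-11 and 4.7e-15 with the block. N1N2 replicate 1, on the shared slide, stood apart with the lowest cell cycle mean of its group (-1.97).

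Of the 10 Notch targets and receptors tested, 5 fell and 1 rose, both over all genes and adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.14 with an estimated correlation). Besides Hes1, the Notch-induced genes Nrarp and Dtx1 fell by 0.90 and 0.94 on the log2 scale, Heyl fell by 0.34 and Notch2 by 0.55, while Notch4, a receptor known mainly from endothelium, rose by 0.87. Notch1 differed by 0.03 (adjusted p = 0.94). With slide as a block the list's median was -0.27 and did not pass (adjusted p = 0.058). Immune cell markers were lower as a list (camera adjusted p = 0.017, and adjusted p = 0.40 with an estimated correlation), and 2 of 17 members, Gzma and Cd3e, fell over all genes and 4 adjusted over the list alone; with slide as a block the list did not pass (adjusted p = 0.26). Their median was -0.30 over all arrays and -0.23 within the shared slide.

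Stem cell genes split. Ascl2, a transcription factor of crypt base stem cells, fell by 1.45 on the log2 scale (SE 0.24, adjusted p = 0.0014) and Slc14a1 by 1.13, whereas Phlda1 rose by 1.60 and Sox9 by 0.94, the latter not with slide as a block (0.49, adjusted p = 0.29). Lgr5, the receptor that marks crypt base stem cells, changed by -0.55 and did not pass the test (adjusted p = 0.16). Over the 21 members tested, 7 fell and 2 rose over all genes, and 8 fell and 4 rose adjusted over the list alone, and the list as a whole did not pass over all arrays (camera adjusted p = 0.11) but did with slide as a block (median -0.38, adjusted p = 0.0024). Axin2, a direct Wnt target, changed by 0.14 (adjusted p = 0.75), and its second probe had the opposite sign. Among 19 Wnt targets 2 rose and 2 fell (adjusted over the list alone, 2 rose and 3 fell). Wnt3, the Wnt ligand made by Paneth cells, rose by 1.90 on the log2 scale, and Rspo1, an R-spondin that amplifies Wnt signals, fell by 1.29. Neither passed with slide as a block (Wnt3 1.40, adjusted p = 0.078; Rspo1 -1.53, adjusted p = 0.23).

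Few markers of mature cell types other than goblet cells passed the test. Among 28 enteroendocrine markers, 3 rose, namely Rfx6 by 2.20, Pcsk1 by 0.88 and Isl1 by 0.47, while the hormone-granule gene Chga changed by 0.26 (adjusted p = 0.21). Lyz1, a Paneth cell lysozyme, changed by 0.04 (adjusted p = 0.95), Fabp1, an enterocyte fatty acid binding protein, by 0.19 (adjusted p = 0.58), and Dclk1, a tuft cell marker, by -0.22 (adjusted p = 0.32). In the Paneth, enterocyte and tuft cell lists 1 member each passed, Copz2 (-0.27) of 12, Ada (-0.94) of 24 and Trpm5 (0.39) of 15. Among stromal and muscle markers, 2 of 18 fell, the matrix genes Dcn and Lum, by 1.38 and 1.27 on the log2 scale. The 12 lists that did not pass camera had adjusted p-values from 0.069 for enteroendocrine markers to 0.93 for p53 targets.

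Among genes whose groups did not overlap, those that rose most, after Neurog3, were Cbfa2t3 (log2 change 2.52), Gfra3 (2.44), the co-repressor subunit Rcor2 (2.42), the receptor tyrosine kinase Kit (2.41) and the calcium channel Cacna1a (2.25). The second probe for Cbfa2t3 had the opposite sign. Those that fell most under the same condition were the retinol-binding protein Rbp7 (log2 change -3.19 ± 0.16 SE, adjusted p = 5.5e-08), the xenobiotic-metabolising enzyme Cyp1a1 (-1.75), the glucuronosyltransferases Ugt2b5 (-1.74), Ugt2b38 (-1.58) and Ugt2b36 (-1.47), and Cnn3 (-1.51). Members of the Ugt2b family are close in sequence, and their probes could take up each other's RNA. Within the shared slide, and with slide as a block, Neurog3 changed by 3.30, Rbp7 by -3.45 and Hes1 by -1.15, and all 3 passed the test. With that block 256 genes passed in place of 2805, of which 239 were among the 2805, and 31 of the 57 genes picked for naming that had passed did not. Those 31 include Atoh1 (1.31, adjusted p = 0.060), Cyp1a1 (-2.37, adjusted p = 0.070), Ern2 (1.42, adjusted p = 0.069), Rfx6 (1.73, adjusted p = 0.053), Mcm3 (-0.94, adjusted p = 0.073), Dtx1 (-0.94, adjusted p = 0.22), Notch4 (0.54, adjusted p = 0.21), Notch2 (-0.41, adjusted p = 0.32), Dcn (-0.75, adjusted p = 0.57) and Lum (-0.98, adjusted p = 0.47). Mcm6, Birc5, Pdia4, Atf4, Pcsk1, Isl1, Gzma, Cd3e, Copz2, Ada and Trpm5 are among them too. Only 4 arrays inform the difference in that fit, and several of these genes changed about as much there, such as Mcm6 (-0.91), Birc5 (-0.86) and Atf4 (0.74), so a lost call does not show that slide explains the change. Leaving out control replicate 2, control replicate 5 or N1N2 replicate 4 left 1545, 1552 or 1597 genes, and centring each array on its median in place of loess left 1259 and moved the share that rose from 56.0% to 45.5%.

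The second comparison addressed what the Lrp6 antibody changed in crypts already under Notch blockade. Most cell cycle genes rose, and some of the secretory genes fell. Of 25 cell cycle genes, 22 rose and none fell over all genes, and 23 rose adjusted over the list alone (camera adjusted p = 1.5e-18, and adjusted p = 0.17 with an estimated correlation). Mcm6 rose by 0.99, Mcm3 by 0.95, Cdk1 by 0.94 and Birc5 by 0.87 on the log2 scale, whereas Mki67 changed by 0.06 (adjusted p = 0.85). The second probe for Mki67 had the opposite sign. Ascl2 was 2.50-fold higher than with the Notch antibodies alone (log2 change 1.32 ± 0.24 SE, adjusted p = 0.0026, n = 5 per group). Hes1 rose by 0.54 (SE 0.13, adjusted p = 0.011). In all, 2260 features rose and 1736 fell, 47 and 152 of them at least 2-fold. Of these 3996 features, 2648 had a gene name.

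Unfolded protein response genes fell in 11 of 16 cases over all genes and in 12 adjusted over the list alone, with none higher (camera adjusted p = 7.55e-10). Pdia6 and Ern2 each fell by 1.27 on the log2 scale and Herpud1 by 0.70; Atf4 fell by 0.51 but was at 0.11 with median centring in place of loess. Of the 13 secretory progenitor genes 6 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.2e-06). Gfi1 fell by 1.27, Dll1 by 1.06, Spdef by 0.96 and Atoh1 by 0.92, while Neurog3 changed by -0.54 and did not pass (adjusted p = 0.20). Of 18 goblet cell markers 6 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 1.2e-06), led by Sytl2 (-1.25) and Pdia5 (-0.95). With arrays scaled to each other the goblet list had a median of 0.16 and did not pass (adjusted p = 0.66). None of the list calls of this comparison held with an estimated correlation. For the unfolded protein response, secretory progenitor and goblet cell lists camera gave adjusted p = 0.17 with an estimated correlation. Fry gave these lists adjusted p = 0.0018, 5.8e-04 and 0.0025. It gave 5.8e-04 for the cell cycle list and 0.44 for the enterocyte list, which did not pass.

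Stromal and muscle markers fell in 7 of 18 cases over all genes and in 8 adjusted over the list alone (camera adjusted p = 3.6e-04, adjusted p = 0.56 with an estimated correlation and 0.058 with fry). The collagen genes Col1a2 and Col1a1 fell by 0.88 and 0.79 and smooth muscle actin Acta2 by 0.81 on the log2 scale. The groups that differed in these markers also differed in the cell cycle, secretory and unfolded protein response genes. With the stromal mean of each array as a covariate, the median of the cell cycle list was 0.57, against 0.78 without it. How the list means correlate from array to array was not computed. Enterocyte markers had a median of -0.24 (camera adjusted p = 0.030, and adjusted p = 0.93 with an estimated correlation), with 1 of 24 lower over all genes and none adjusted over the list alone, and a median of 0.46 when the arrays were scaled to each other.

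Neither Wnt list passed the test. The 20 Wnt receptors and ligands had a median of -0.12 (camera adjusted p = 0.13), with 15 below 0 and 1 past the threshold, both over all genes and adjusted over the list alone. Among 19 Wnt targets, Ascl2, Ccnd1 and Myc rose, by 1.32, 0.64 and 0.72 on the log2 scale, and Nkd1, a feedback inhibitor of Wnt signalling, fell by 0.61 (the counts were equal adjusted over the list alone; camera adjusted p = 0.97). Axin2 changed by -0.39 (adjusted p = 0.28) and Lgr5 by -0.66 (adjusted p = 0.079). The antibody target Lrp6 itself changed by -0.31 (adjusted p = 0.26). The second probes for Axin2 and for Lrp6 had the opposite sign. Wnt3 fell by 1.21. In the stem cell list 5 of 21 rose and 1 fell (5 and 3 adjusted over the list alone), with Slc14a1 at 1.19 and Phlda1 at -0.68, and the list did not pass (camera adjusted p = 0.56). The 12 lists that did not pass had adjusted p-values from 0.13 to 0.97.

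Sftpc and Sftpa1, which encode surfactant proteins of the lung, were among the genes that rose. Sftpc was 5.34 higher on the log2 scale than in the N1N2 group (SE 0.57, adjusted p = 0.00025; n = 5 and 4, because the Sftpc spot of N1N2 replicate 3 was left out for an uneven local background). In the authors' deposited values, which hold that spot, the difference was 5.04. Sftpa1 was not well above background on any N1N2 or control array, so no fold is given; it was higher than in the N1N2 group at adjusted p = 0.00046. Of the other genes whose groups did not overlap, those that rose most were Rbp7 (log2 change 2.29), the mitotic kinase Pbk (1.61), Cnn3 (1.48) and Shmt1 (1.41). Those that fell most were the fucosyltransferase Fut2 (-1.72), Slc17a9 (-1.55), Wtip (-1.51), Tnfrsf25 and the noncoding RNA Airn (-1.47 each) and Cbfa2t3 (-1.43); Fut2 was well above background on 4 of the 5 N1N2 plus Lrp6 arrays.

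No slide held both groups of this comparison, so a shift between slides could not be separated from the treatment. The count of 3996 became 2514 without N1N2 replicate 4, and 402 with the stromal mean as a covariate. It was 2621 without both the late-scanned N1N2 replicate 3 and N1N2 plus Lrp6 replicate 1. The latter had the fewest spots above background. With median centring 77.2% of the calls were higher, against 56.6% with loess.

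The changes of the first and second comparisons ran in opposite directions. All 1884 features that passed both tests changed in opposite directions, 1061 of them higher and then lower and 823 lower and then higher, and none changed the same way in both. The count was 1009 without N1N2 replicate 4, 843 with median centring and 380 with the stromal mean as a covariate. Independent lists of these sizes would share 114 and 116 genes in the opposite directions and 148 and 89.4 in the same directions. The lists here are not independent, because the same N1N2 arrays enter both differences with opposite sign. That favours opposite calls and disfavours calls in the same direction. Rbp7, Ascl2, Hes1, Mcm3, Mcm6 and Birc5 fell and then rose; Atoh1, Dll1, Spdef, Gfi1 and Ern2 rose and then fell. Across genes, which are not independent replicates, the log2 changes correlated with r = -0.768. Because the N1N2 arrays enter both differences with opposite sign, simulated groups with no effect gave a mean r of -0.526 (100 simulations, range -0.930 to 0.212). The covariance was -0.0707, against -0.0143 in the simulations (range -0.0629 to 0.0058), a difference of -0.0564. With the N1N2 arrays split so that each difference used its own, r averaged -0.584 over 20 splits (range -0.728 to -0.342) and between 243 and 763 genes passed both tests in opposite directions, with at most 41 in the same direction. The split does not remove a shift that all N1N2 arrays share.

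**Figure D2:**
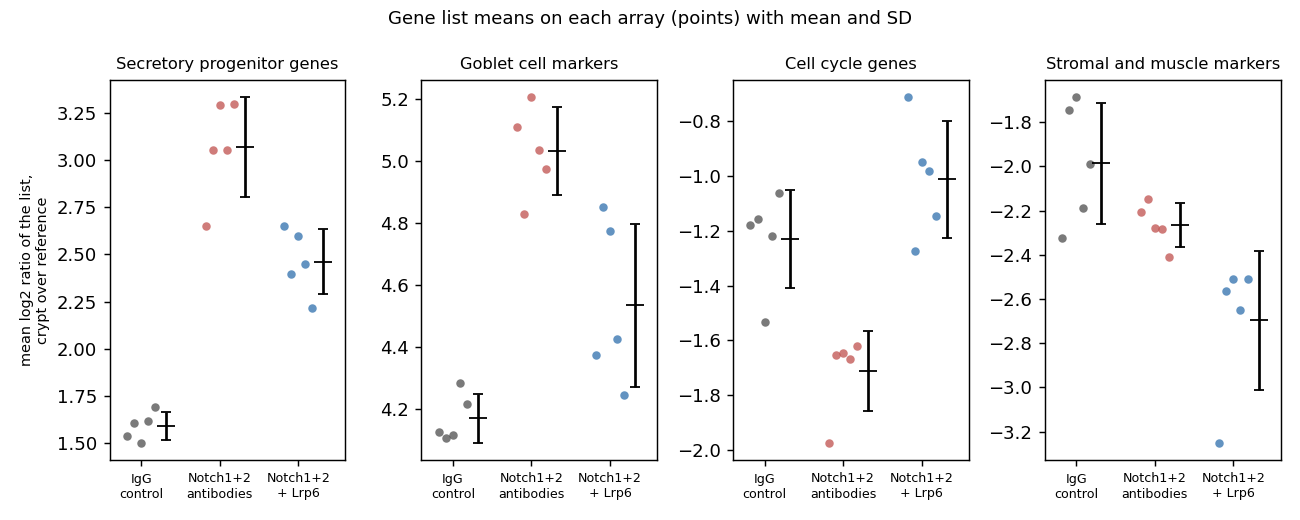
Mean log2 ratio of crypt over reference RNA (vertical axes) over the tested members of 4 gene lists on each array of the 3 groups; points are single arrays, the bar beside them is the mean and the whisker its SD. The cell cycle mean lies between -1.97 and -1.62 on the N1N2 arrays, between -1.53 and -1.06 on the control arrays and between -1.27 and -0.71 on the N1N2 plus Lrp6 arrays.

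The third comparison asked what difference from control remained when both treatments were combined. Few genes passed the test, and those with the largest rises included secretory progenitor genes. Neurog3 stayed 9.76-fold above control (log2 change 3.29 ± 0.27 SE, adjusted p = 3.0e-05, n = 5 per group), Gfra3 3.94-fold and Insm1, a factor of endocrine differentiation, 3.23-fold. Lgr5 was lower than in control crypts (log2 change -1.21 ± 0.24 SE, adjusted p = 0.046). In all, 53 features rose and 37 fell, 20 and 17 of them at least 2-fold, and 83 of these 90 had a gene name. Of the 23937 features, 3112 had an unadjusted p under 0.05. A gene that did not pass is therefore not shown to be back at its control level.

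Of the 13 secretory progenitor genes 7 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 2.1e-13, and adjusted p = 0.029 with an estimated correlation). Besides Neurog3 and Insm1 these included Sox4 (1.19), Pax4 (1.14), Spdef (0.95) and Dll1 (0.75), while Atoh1 was at 1.03 and did not pass (adjusted p = 0.095). Of 18 goblet cell markers 2 rose over all genes, Creb3l4 (0.95) and Creb3l1 (0.74), and 10 adjusted over the list alone (camera adjusted p = 1.4e-07, and adjusted p = 0.12 with an estimated correlation). No Notch target or receptor passed over all genes, and 3 of 10 fell adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.035 with an estimated correlation); Nrarp was at -0.63 and Dtx1 at -0.80. No cell cycle gene passed over all genes and 2 rose adjusted over the list alone (median 0.20, camera adjusted p = 2.4e-06, and adjusted p = 0.41 with an estimated correlation). Enteroendocrine markers had a median of 0.12 with no member past the threshold over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.032, and adjusted p = 0.41 with an estimated correlation).

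Stromal and muscle markers were lower in crypts given both treatments. Of 18 members, 3 fell over all genes, namely Col1a1 (log2 change -1.15), Col3a1 (-1.31) and Actg2 (-1.44), and 12 adjusted over the list alone (camera adjusted p = 3.2e-13, and adjusted p = 0.073 with an estimated correlation). Immune cell markers had a median of -0.30 with no member past the threshold over all genes and 2 lower adjusted over the list alone (camera adjusted p = 2.8e-04, and adjusted p = 0.15 with an estimated correlation). The other 11 lists did not pass, with adjusted p-values from 0.066 for immediate early and heat shock genes to 0.81. In the stem cell list Phlda1 rose by 0.92 and Lgr5 and Fstl1 fell (2 higher and 2 lower adjusted over the list alone).

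Sftpc, well above background on only 3 of the 5 control arrays, was higher than in control (log2 change 4.24 ± 0.54 SE, adjusted p = 0.0035), Sftpa1 was also higher (adjusted p = 0.0049), and the chemokine Ccl9 was 2.84-fold higher. Among the genes that fell most without overlap of the groups were the iron transport genes Cybrd1 (-1.59) and Slc40a1 (-1.56), the phosphatase Akp3 (-1.55), Msln (-1.47) and Actg2 (-1.44); Cybrd1 and Actg2 were well above background on 4 of the 5 N1N2 plus Lrp6 arrays.

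Of the 23 genes picked for naming that passed here, 14 no longer did when 1 array was left out, Lgr5, Cybrd1, Slc40a1, Akp3, Msln and Actg2 among them. The count of 90 also moved with single arrays: it was 27, 28, 36 and 26 without control replicates 2, 3, 4 and 5, 53 without N1N2 replicate 4, and 52, 42, 26, 30 and 348 without N1N2 plus Lrp6 replicates 1 to 5 in turn. Replicate 5 was the only array of its group on another slide, so the 348 come from a group that lay on a single slide. Whether slide accounts for that rise was not tested. No slide held both groups, the stromal mean as a covariate left 1 gene and turned the median of the cell cycle list to -0.12, and the share that rose went from 58.9% to 72.7% with arrays scaled to each other and to 38.4% with the scanner software's log ratios.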

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

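Within each group of 5 arrays, 336 sets of values (named genes, list means and the share of bright spots in 3 groups) were searched for an array far from the others of its group, and 18 were found. Chance alone gives about 1 in 20 of independent sets, which is close to this total. The sets are not independent, and that rate does not address how many fell on the same array, N1N2 replicate 1 above all. No explanation was weighed for any of them.

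N1N2 replicate 1 stood apart in 7 sets of log2 ratios. It was lower than the other N1N2 arrays for Cbfa2t3 (2.99, others from 3.61), Pax4 (1.82, others from 2.68), Creb3l1 (1.16, others from 1.55), Rfx6 (2.17, others from 3.36), Gfi1 (0.91, others from 1.65) and the mean of the cell cycle genes (-1.97, others from -1.67). It was higher for Lcn2 (-0.88, others up to -1.25). The array thus had the smallest values of several secretory genes in its group, and for each of these it still lay above all control arrays.

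N1N2 plus Lrp6 replicate 1, the array with the fewest spots above background, was lowest in its group for Actg2 (-3.96, others from -2.32), Fstl1 (-7.09, others from -6.32) and the mean of the stromal and muscle markers (-3.25, others from -2.65), and highest for the mean of the interferon response genes (0.28, others up to -0.07). Replicate 5 of the same group was lowest for Gfra3 (3.43, others from 4.27).

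N1N2 replicate 5 was highest in its group for Rbp7 (2.66, others up to 2.03) and N1N2 replicate 3 for Wtip (1.85, others up to 1.06). Control replicate 3 was lowest for Mcm7 (-1.65, others from -1.25) and Ccng1 (-1.53, others from -1.28) and highest for the mean of the unfolded protein response genes (1.28, others up to 0.96). Control replicate 1 was lowest for Pdia4 (0.63, others from 1.12).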

How the results depend on the processing

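The first normexp version, the stromal covariate and leaving out the late-scanned array with the array of fewest spots above background were chosen after seeing the data. In the order N1N2 against control, N1N2 plus Lrp6 against N1N2, and N1N2 plus Lrp6 against control, the counts were 2805, 3996 and 90, with 1884 opposite calls at r = -0.768. The first normexp version gave 2456 (70.1% higher), 2339 and 49 (87.8% higher), sharing 1882, 2326 and 40 with the corrected fit, with 1205 opposite calls at r = -0.582, and turned the enterocyte list in the third comparison to 0.52; the compressed ratios of 4 arrays account for it by construction. The deposited table, in which those arrays are not compressed, gave 2820, 4008 and 86. The scanner software's log ratios gave 138 in the third comparison, 1239 opposite calls at r = -0.638, and Mgam at 0.028 in the second. Median centring gave 1259 and 30 in the first and the third comparisons, 843 opposite calls, and Atf4 at 0.11 in the second. Scaling between arrays gave 55 in the third, turned Paneth (-0.49) and enterocyte (-0.58) lists and Anxa1 (0.052) in the first and the enteroendocrine (0.18) and enterocyte (0.46) lists in the second, where the goblet list was at 0.16 and no longer passed. The cause of these was not tested.

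Fitting only the 2 groups gave 50 in the third comparison. Slide as a fixed block gave 256 in the first, from a fit in which only 4 arrays inform the difference. Slide as a random block gave 7034 and 2912 in the second and the third and 3017 opposite calls; its estimated correlation within slides was -0.182, a negative value that adds calls, so these counts are not read as stronger evidence. Array weights gave 6095 and 407 in the first and the third and 3450 opposite calls. Requiring at least 1.5-fold gave 1202 and 1410 in the first and second and 728 opposite calls, and an adjusted p under 0.01 gave 994, 1620 and 22 with 602 opposite calls; fewer genes pass a stricter limit by construction. The stromal covariate gave 4442, 402 and 1, with 380 opposite calls at r = -0.628, and in the third comparison the cell cycle list at -0.12 and the unfolded protein response and defence lists at 0.59 and 0.38. It raised the median SE 1.12, 1.27 and 1.64 times, since stromal content differs between groups. Without the late-scanned array and the array with the fewest spots above background the counts were 3575, 2621 and 46. With the N1N2 arrays split, r averaged -0.584 and the median was 418 opposite calls. Camera passed 6, 6 and 7 lists; with an estimated correlation it passed 2, 0 and 2, and fry 4 in the third.

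Leaving out each array in turn gave 1545 to 3902, 2514 to 4740 and 26 to 348 calls, 1009 to 2403 opposite calls at r from -0.808 to -0.695, and 5 to 7, 5 to 8 and 6 to 13 lists. The replicate numbers were not taken to pair the samples, since in no comparison did every same-numbered pair correlate over 0.1; 4 of 15 did. These 4 were all between control and N1N2 arrays (0.622, 0.285, 0.383 and 0.135; the other pair -0.0103), as were the 3 arrays that correlated best with their own number, and the 10 pairs with the Lrp6 group ranged from -0.433 to 0.0974. With the replicate number as a block the counts were 2433, 3707 and 44. Of the named genes that passed, 10 of 57, 8 of 52 and 14 of 23 lost their call without 1 array, and none with the deposited table. That table holds nearly the same values as those used here, so the latter does not test stability. With the stromal covariate 4, 23 and 23 of them lost it, and with slide as a fixed block 31 of the 57. Over all named genes and lists, 8739 values stayed on their side of the threshold, 636 no longer passed, 222 newly passed, and 11 that passed in either fit changed direction; values short of the threshold in both could change sign. Signal limits the N1N2 plus Lrp6 arrays most, where between 57.2% and 73.6% of spots were above background. The 73.6% is from replicate 5, the only array of that group on another slide.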

Other observations

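The deepest fall of any feature in the N1N2 group was in probe A_52_P607507, chosen after its values were seen, for which the tables used here give no gene name. Its log2 ratio was 4.54 ± 0.40 in the control group, 0.46 ± 0.26 in the N1N2 group and 0.93 ± 0.45 in the N1N2 plus Lrp6 group (SD, n = 5 each). It fell by 4.08 with the Notch antibodies (adjusted p = 5.5e-08), and adding the Lrp6 antibody changed it by 0.47, which did not pass the test (adjusted p = 0.16). Unlike Rbp7, which fell by 3.19 and rose by 2.29, this probe thus stayed 3.61 below control on the log2 scale (log2 change -3.61, adjusted p = 6.7e-07).

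Neurog3 and Insm1 kept most of their rise when the Lrp6 antibody was added, whereas Gfi1 and Ern2 did not. Neurog3 was 3.83 above control with the Notch antibodies and 3.29 with both treatments, and Insm1 1.74 and 1.69; Gfi1 went from 1.79 to 0.52 and Ern2 from 1.81 to 0.54. Whether the part that was lost differs between these genes was not tested. Among p53 targets, Mdm2 rose by 0.43 and then fell by 0.50, and Ccng1 fell by 0.62 and then rose by 0.62, so that this list held changes in both directions. With slide as a block the rise of Mdm2 was 0.40 and did not pass (adjusted p = 0.15). The fall of Ccng1 was -0.73 there and passed (adjusted p = 0.049). In the defence list Retnlb, a resistin-like protein of goblet cells, rose by 1.81 and then fell by 1.28; with slide as a block the rise was 0.85 and did not pass (adjusted p = 0.25).

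The predictions for the tests below were written after gene results of the first version and before the values they test, except the stromal test of the cell cycle list in the first comparison alone, which was chosen after its result was seen. The reading of the lung marker test, of the slide test with 1 array and of the Sftpc test of aberrant arrays was made stricter after their values were seen: a bound had to be passed by more than the spread, and neither 1 array nor a gene chosen for its lack of overlap was taken as deciding.

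Surfactant genes rose in crypts given the Lrp6 antibody as well. Sftpc was higher on 5 of the 5 N1N2 plus Lrp6 arrays (at least 3.63) than on any of the 9 other arrays with a value (at most 2.22). Genes with the largest changes were taken only where the groups did not overlap, so this was set by the choice of the gene and does not decide whether 1 or 2 aberrant arrays play a part. RNA carried over from lung could explain these genes: of 14 other lung markers, the median difference from the N1N2 group was 0.186 (range -0.74 to 0.71), with Sftpd at 0.71 and Scgb1a1 at 0.43, while Sftpb was above background on 1 of the 5 arrays. That median lies below the planned limit of 0.2 by less than its standard error of 0.093, and a small share of lung RNA would show only in its most abundant transcripts, so lung RNA and a response of the crypts cannot be told apart. Sftpc was also well above background on 3 control and 4 N1N2 arrays.

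Many secretory and goblet genes rose with the Notch antibodies, while the stromal list had a median of -0.27 and did not pass (adjusted p = 0.13). With the stromal mean as a covariate, 95% of the called members (19 of 20) stayed past the threshold in the same direction, which argues against stromal content as the whole cause. Within the slide that held both groups, their median was 0.763 of that over all arrays (0.91 against 1.20), which argues against a difference between slides as the whole cause. A response to the Notch antibodies is thus the hypothesis left among those tested, found and tested on the same arrays.

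Most cell cycle genes fell with the Notch antibodies and rose when the Lrp6 antibody was added. For the fall, the median within the shared slide was -0.770. The cell cycle means there were -1.97 and -1.65 on the N1N2 arrays and -1.22 and -1.06 on the control arrays. The -1.97 is from N1N2 replicate 1, which stood apart for this list and enlarges the fall on that slide. With the stromal covariate the median over all arrays kept 1.25 times its size (-0.68 against -0.55). These values argue against both slide and stromal content as the whole cause. For the rise, the covariate left 0.724 of the median (0.57 against 0.78), between the limits set for the 2 comparisons together, so that part of it may follow the stromal content. No slide held both groups there; the 1 N1N2 plus Lrp6 array on a slide of its own had a cell cycle mean of -1.15, above the N1N2 arrays (-1.97 to -1.62), but as a single array it leaves slide and the Lrp6 antibody open. The list's call in either comparison was lost with an estimated correlation. With fry the list passed in both (adjusted p = 0.0046 and 5.8e-04).

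Regrouping the arrays tested whether a random division of them gives such counts. Among features with a value on every array, 2766 passed in N1N2 against control, 3954 in N1N2 plus Lrp6 against N1N2 and 88 in N1N2 plus Lrp6 against control. Of 100 splits of the same arrays in each comparison, 1 gave as many, the real one, and the highest count of the others was 6, 1115 and 2. A random division of the arrays is thus an unlikely source of these counts, at 1 in 100, the smallest share this test could give. The test does not show how stable the counts are, and slide remains confounded with group in the second and the third. Which split gave 1115 calls was not recorded. A split that exchanges few arrays still largely separates the treatments, so this count does not show structure within the groups.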
